A study of Drosophila melanogaster with 23 samples.

How the data were processed

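ATAC-seq libraries of 14 samples of tagged nuclei and 8 samples of whole embryos were analysed, and 1 further sample, genomic DNA, was not analysed here. The authors supplied a single peak list per library on genome build dm3. Per the labels, they aligned reads with Bowtie2 2.2.9, handled them with SAMtools 1.3.1 and called peaks with MACS2 2.1.1.2, with the genomic DNA library as reference. Each peak had the authors' score, which was within 1 of 10 times its -log10 q in 100% of the peaks of every list, and no peak had a -log10 q below 2. The authors' fold enrichment over the reference at the peak summit and the authors' -log10 q were used only to rank, filter or describe peaks. Other settings of the authors, such as a shift of reads for the transposase, were not stated, and read depth was unknown, so no interval or detection limit was computed from counts.

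The lists were of 2 kinds. In 8 lists (replicate 1 of D1, D4, D5 and D7, tagged and whole embryo) no peak name carried a letter, while the other 14 lists held 5020 to 6305 lettered peaks, 28.4% to 32.6% of each list, none of them lettered a. The summit of a lettered peak lay at a median of 77.9% to 78.7% of its length and that of other peaks at 49.5% to 49.7%, so for peaks with several summits these lists appear to hold the values of a late one. Ranking by strength therefore differed between the kinds of list, and ranking by width was added. Library names were written in 3 styles, with 4, 7 and 3 of the tagged libraries, and the first style was that of the 8 lists with no lettered peak. Style was treated as a possible batch.

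Peaks on X, 2L, 2R, 3L, 3R and 4 from all 22 lists were merged where they overlapped by at least 1 bp, and a region counted as found in a library that had a peak in it. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used, and matplotlib 3.10.9 for the plots. The 7 domains were ordered D1, D3, D2, D4, D5, D6, D7 by the known positions of their enhancers, and grouped as anterior (D1, D2, D3), central (D4, D5) and posterior (D6, D7). Regions found in at least 2 and missing from at least 2 of the libraries compared were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A region was called fully separated when it was found in every library of one side and in none of the other, a count added after the results of that test were seen. Tagged nuclei of D1, D4, D5 and D7 were compared with whole embryos of the same constructs.

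The groups, tests, alternatives and the rule for naming regions were chosen before the data were examined, except where stated. The rule named the loci of the 5 genes whose enhancers drive the tag, for each comparison and direction the 10 called regions with the smallest p, ties broken by the authors' fold, and genes of fixed lists with a called region. As 0 regions were called, regions were named in the order of that rule and by position. The genes in the annotation used here are placed on a later build than dm3, so 0 regions were linked to genes, and the gene lists, cell type markers, driver loci and motif content were not tested.

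Overlap of lists was measured as the base-pair Jaccard index and tested by 100000 random re-pairings of libraries. Axis distance was tested over all orders of the domains. Counts of regions gained or lost in a domain were tested over the 45 choices of 2 of 10 libraries, one-sided, with Benjamini-Hochberg adjustment over 7 domains. The median of the authors' -log10 q of a list was set against lost or missing regions with exact permutations, a comparison added after the counts were seen. Lost regions shared by domains were compared with draws within 50 classes of like median fold in the whole-embryo lists, also added later (one-sided, adjusted over 21 pairs). Alternatives were lists of equal length (16830 peaks, by strength or width), the strongest or widest 50% of each list, an overlap of 50%, bins of 500 bp, no filter, all sequences, strata by replicate number, strain or naming style, and each library left out in turn. Splits of the libraries were drawn 100 times, or the domains were divided in all 35 or 21 ways.

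Pairing by strain followed the labels and was checked. After the mean of the tagged and that of the whole-embryo libraries had been subtracted, tagged libraries correlated with the whole-embryo library of the same strain at a mean of 0.179 (range 0.00257 to 0.344) and with those of other strains at -0.0254, and 7 of 8 were most correlated with their own. Replicate numbers did not pair libraries across domains (mean correlation 0.0267). On simulated data with 200 regions set to full separation, all 200 were recovered in each of the 4 comparisons with 0 to 4 false calls. As 200 is above the number needed for a call in each (29 to 186), this checked the computation and not the power at the numbers observed. Regions present in 0.9 of the libraries of one side and 0.1 of the other were recovered in 21% of cases in the comparison of tagged nuclei with whole embryos and in 0% in the other 3, so regions that differed in most but not all libraries were mostly missed, and a call also depended on the number of separated regions.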

Results

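Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in nuclei of stage-5 Drosophila blastoderm embryos. In 7 sets of transgenic strains an enhancer of a patterning gene drove a FLAG-tagged nuclear envelope protein in a band of the embryo, and the tagged nuclei were collected with an anti-FLAG antibody. The band called D1 was set by the anterior enhancer of hunchback, D3 by the enhancer of the first even-skipped stripe and D2 by that of its stripe 2. Dichaete and Kruppel enhancers set the central bands D4 and D5, the enhancer of even-skipped stripe 5 set D6, and the posterior enhancer of giant set D7. Each of the 7 domains had 2 libraries of tagged nuclei, 14 in all. The controls were 8 libraries of all nuclei of the embryo, 2 for each of the constructs D1, D4, D5 and D7, made without the pull-down. Each library was represented by a list of accessible regions, called peaks, and read depth was unknown, so list length, covered length and the authors' -log10 q of the peaks were the measures of how much had been detected in a library. P-values of tests over libraries measured the spread between libraries of transgenic strains, and both D3 libraries carried the same strain label. Other p-values rested on random draws of regions, counts of regions or orders of the domains, and did not measure that spread.

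The lists held between 16830 peaks (D6 replicate 1) and 22169 peaks (D1 replicate 1) on chromosome arms X, 2L, 2R, 3L, 3R and 4. The means of the 2 lists of a domain were lowest in D6 (17364), D7 (18249.5) and D3 (18281.5), and D3 replicate 2 (17412) and D2 replicate 2 (17863) were shorter than 3 of the 4 posterior lists. Tagged libraries covered 10.3 to 14.5 Mb, and the median of the authors' -log10 q in a tagged list ran from 20.3 to 55.0. The 2 D4 lists held 21284 and 19184 peaks, and those of D5 held 21183 and 19551. In the 4 constructs with both kinds of library, tagged nuclei gave 19873 ± 1491 peaks (SD, n = 8) and whole embryos 20472 ± 624 (SD, n = 8). The difference of -598.5 peaks was within the spread between libraries (exact permutation test, two-sided, p = 0.304), and tagged nuclei gave fewer peaks in 5 of 8 strains (exact sign-flip test over strains, two-sided, p = 0.266). Within the naming style of the replicate 1 libraries, a possible batch, the differences by strain were 1249 (D1), 1634 (D4), 182 (D5) and -2254 (D7) peaks, and within that of replicate 2 they were -831, -1880, -1246 and -1642.

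**Figure D1:**
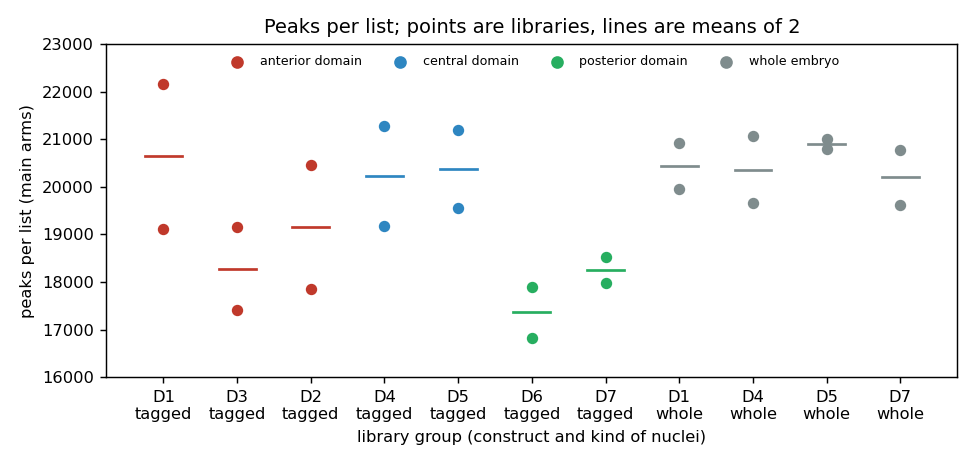
Number of peaks per list (vertical axis, peaks on the main chromosome arms) for each group of libraries (horizontal axis). Points are single libraries and lines are means of 2, with D6 lowest at 16830 and 17898 peaks.

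Merging the peaks of all 22 lists gave 25311 regions with a median width of 480 bp. A common set of 10843 regions (42.8%) was found in all 22 libraries, and 2579 (10.2%) were found in 1 library. Regions found everywhere had a median width of 865 bp, against 223 bp for regions found in 1 library. The median over regions of the authors' highest fold enrichment in any library was 6.15 against 1.65. Width was that of the merged peaks and fold the highest of any library, so both can rise with the number of libraries alone. Of the 24204 regions found in tagged nuclei, 10927 (45.1%) were found in all 14 tagged libraries. Both libraries of a domain shared from 76.6% (D1) to 82.7% (D4) of the regions found in either.

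Whether the peak sets of a domain resembled each other more than those of different domains was asked first. The base-pair overlap (Jaccard index) of the 2 lists of a domain averaged 78.0% ± 2.35 (SD, n = 7 pairs) and ranged from 74.7% in D1 to 81.7% in D4. Lists of different domains overlapped by 74.8% ± 3.17 (SD, n = 84 pairs). The gap of 3.22 percentage points was larger than random re-pairing of the libraries gave (permutation test, 100000 re-pairings, two-sided, p = 0.00125). Libraries whose names were written in the same style overlapped more across domains than those of different styles, at 76.3% (n = 30 pairs) against 74.0% (n = 54 pairs; permutation test, two-sided, p = 0.0055). The libraries of a domain always differed in style, with 1 of them in the style of 7 tagged libraries. Among pairs made of 1 library of that style and 1 of another, those of a domain overlapped by 78.0% (n = 7 pairs) and those of different domains by 74.7% ± 3.05 (SD, n = 42 pairs), a gap of 3.30 points (exact permutation over all matchings, two-sided, p = 0.00238), a comparison added after the data were seen.

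Similarity did not follow distance along the embryo beyond what random orders of the domains gave. The most alike pair was D4 and D5, the 2 central domains, at 79.7%, and the least alike were D3 and D5 at 71.3% and D1 and D6 at 71.4%. Over the 21 pairs of domains, in the order D1, D3, D2, D4, D5, D6, D7 from anterior to posterior, Pearson's r between axis distance and overlap was -0.257 (exact permutation of all orders of the 7 domains, p = 0.262) and Spearman's rho was -0.303 (p = 0.185), both two-sided. Without D1 and D7, at the ends of the axis, r was -0.274 (exact permutation of 120 orders, p = 0.467).

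Domain-variable regions, found in both libraries of at least 1 domain and in neither library of another, numbered 5339 (22.1% of the regions found in tagged nuclei). In 99 random pairings of the 14 libraries into 7 pairs the count ran from 2190 to 4987 with a median of 4069, so the true pairing gave the most of the 100 pairings. The count was 3280 with the strongest 50% of each list and 11817 with bins of 500 bp in place of merged regions.

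The anterior domains D1, D2 and D3 were compared with D4 to D7 to ask which accessible regions follow the head-to-tail position of the nuclei. At 29 regions a peak was found in all 6 anterior libraries and in none of the other 8, and at 24 regions it was found in all 8 others and in none of the 6 anterior libraries. These 53 regions are called fully separated. If the 14 libraries were independent, chance would put 0.0333% of regions found in 6 or 8 of them in this state. Libraries of a domain resembled each other, so this share and the Fisher p-values, which treat libraries as independent, are lower than they should be. With domains as units, 1 of 35 divisions is the smallest share possible. The strongest anterior-found regions, by the median of the authors' fold in the anterior lists, lay at X 9660905–9661316 (fold 3.62), 3L 10222068–10222579 (fold 3.54) and 2L 7591533–7592005 (fold 2.93). The strongest regions missing from the anterior lists lay at 3R 12588153–12588529 (fold 3.33), 2L 4312240–4312782 (fold 3.01) and 3R 12512762–12513842 (fold 2.87). These regions were chosen after their values were seen, in an order fixed in advance, and each had p = 0.000333 in Fisher's exact test and an adjusted p of 0.0583.

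A single stretch of 3R, from 12512762 to 12679232, held 9 of the 24 anterior-missing regions. Of its 107 regions, 26 were found in all 22 libraries. Anterior libraries held 38.7 ± 6.74 of the 107 (SD, n = 6, range 26 to 46) and the other tagged libraries 79.5 ± 10.5 (SD, n = 8, range 58 to 95), with whole embryos between them at 59.5 ± 2.00 (SD, n = 8). The domain means were 39 in D1, 33 in D3 and 44 in D2, then 80.5 in D4, 77.5 in D5, 76.5 in D6 and 83.5 in D7. Leaving out the 9 fully separated regions, which were picked for their difference, the other 98 still gave 26 to 46 in the anterior and 49 to 86 in the other tagged libraries. Of the 53 separated regions, 6 of the anterior-found and 14 of the anterior-missing ones were found in all 8 whole-embryo libraries, and 3 anterior-found ones were found in none.

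**Figure D2:**
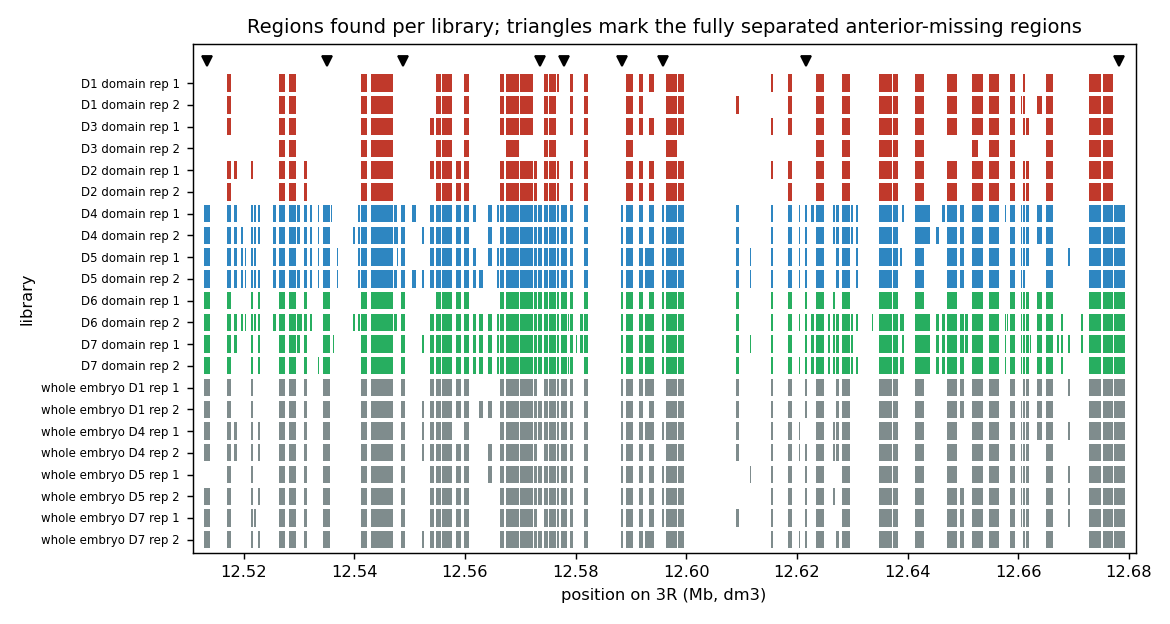
Regions found in each of the 22 libraries (1 line per library) over a stretch of 3R, with position in Mb (dm3) on the horizontal axis and triangles at the 9 regions missing from all 6 anterior libraries. Anterior libraries (red) held 26 to 46 of the 107 regions, central (blue) and posterior (green) libraries 58 to 95, and whole embryos (grey) 57 to 63.

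No single region passed an adjusted p of 0.05 in the anterior comparison. Fisher's exact test on 9284 regions gave 0 calls, with 537 regions at an unadjusted p under 0.05, of which 281 were found more often in the anterior libraries and 256 less often. The smallest adjusted p, 0.0583, belonged to the 53 separated regions, and 62 such regions would have been needed for a call. With the strongest 50% of each list, Fisher's exact test called 50 of 6212 regions (36 found in and 14 missing from the anterior lists, adjusted p = 0.0414), with 3R 11409005–11409692 (fold 5.79) and X 8722848–8723268 (fold 5.24) first among those found and 3R 1541968–1543042 (fold 5.31) first among those missing, but with 60%, 70% or 80% of each list there were 0 calls. Found and missing refer here to the shortened lists, so a region counted as missing may hold a weaker peak in the full list. None of these named regions was among the 53 separated ones of the full lists. Within the shortened lists all 50 were fully separated, and 42 were needed for a call. With any 1 of the 14 libraries left out there were 50 to 66 separated regions but 70 to 95 were needed, and with replicate number or naming style as strata 102 and 296 were needed, so the 0 calls in these settings followed from the design. By peak width in place of strength, the widest 50% of each list gave 47 calls and lists of equal length 54, and without D2 replicate 2 or D6 replicate 1 the separated regions numbered 84 and 82. Among the 7 tagged libraries of 1 naming style, 1 per domain, 236 regions separated the anterior from the other domains, the most of all 35 divisions of the domains, and the other styles held too few tagged libraries (4 and 3).

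**Figure D3:**
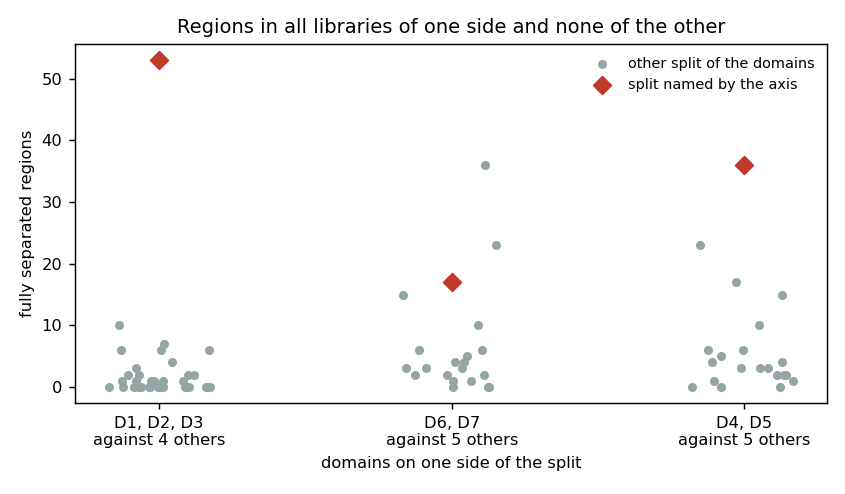
Number of fully separated regions (vertical axis) when the 7 domains are divided into 3 against 4 or 2 against 5 in every way (horizontal axis). Diamonds mark the anterior (53), posterior (17) and central (36) groupings and grey points all other divisions, of which the highest beside the anterior grouping was 10.

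The posterior domains D6 and D7 were compared with the other 5. At 17 regions a peak was missing from all 4 posterior libraries and present in all 10 others, and 0 regions showed the reverse. The strongest of them were X 21153946–21154227 (fold 2.95), 3R 12042273–12042748 (fold 2.81) and 3L 17359020–17359355 (fold 2.46), all 3 chosen after their values were seen. Each was found in all 8 whole-embryo libraries, as were 11 of the 17. Among regions found more often in the posterior domains, 3L 13163369–13163688 and 3R 12625696–12626010 were found in 3 of 4 posterior libraries and in none of the other 10 (Fisher's exact p = 0.0110, adjusted p = 0.641).

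Fisher's exact test on 9284 regions gave 0 posterior calls (smallest adjusted p = 0.546), with 349 regions at an unadjusted p under 0.05, of which 26 were found more and 323 less often in the posterior lists. With lists of equal length 1 region was found in and 6 were missing from the posterior libraries alone, with equal lengths by width 5 and 6, and with bins of 500 bp 3 and 35, so the 0 in 1 direction did not hold in these settings. Without 1 library the count was 44 (D6 replicate 1), 29 (D6 replicate 2), 35 (either D7 library), 34 (D2 replicate 2) or 26 (D3 replicate 2). Within 1 naming style, 294 regions separated the posterior domains, the most but 1 of 21 divisions.

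The central domains D4 and D5 were compared with the other 5. At 36 regions a peak was found in all 4 central libraries and in none of the other 10, and 0 regions showed the reverse. A stretch of 3R from 2750333 to 2835387 held 11 of the 36. Central libraries held 54 ± 2.94 of its 65 regions (SD, n = 4, range 51 to 57), the other tagged libraries 28 ± 4.19 (SD, n = 10, range 19 to 34) and whole embryos 32.2 ± 1.39 (SD, n = 8). Without the 11 separated regions, the other 54 still gave 40 to 46 in the central and 19 to 34 in the other tagged libraries. Outside that stretch the strongest separated regions were X 20548164–20548908 (fold 2.82), X 20556039–20556780 (fold 2.61) and 2R 14113082–14113413 (fold 2.49), again chosen after their values were seen.

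**Figure D4:**
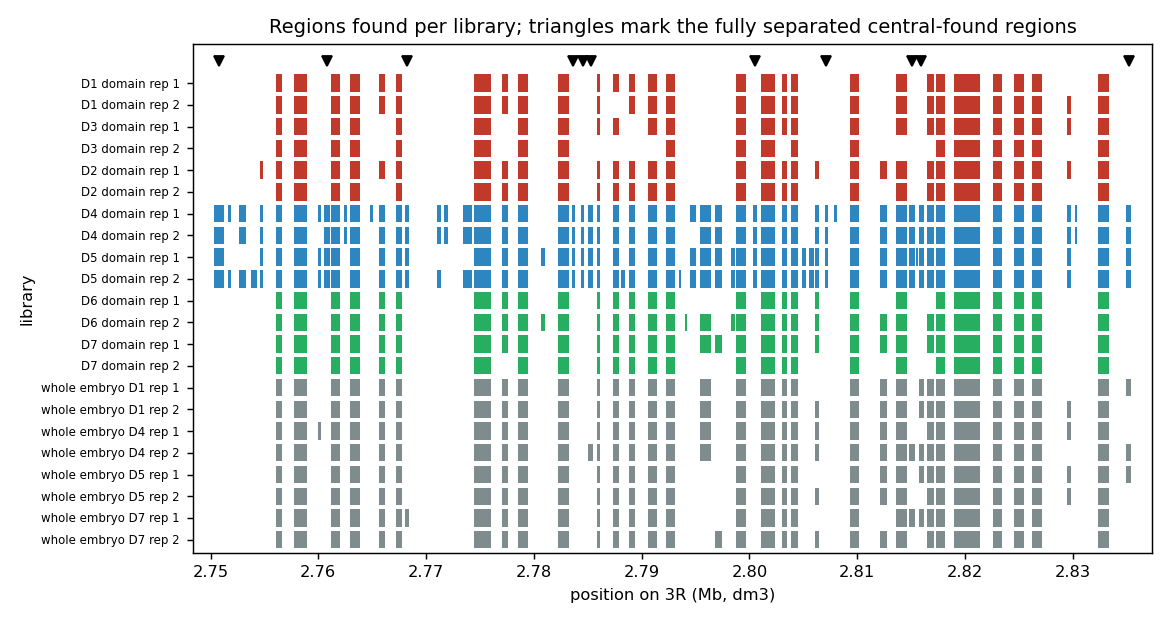
Regions found in each of the 22 libraries (1 line per library) over another stretch of 3R, with position in Mb (dm3) on the horizontal axis and triangles at the 11 regions found in all 4 central libraries and in no other tagged library. Central libraries (blue) held 51 to 57 of the 65 regions, anterior (red) and posterior (green) libraries 19 to 34, and whole embryos (grey) 31 to 35.

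Of the 36 central-found regions, 10 were found in no whole-embryo library and 2 in all 8. Fisher's exact test on 9284 regions gave 0 central calls (smallest adjusted p = 0.258), with 508 regions at an unadjusted p under 0.05, of which 485 were found more and 23 less often in the central lists. A comparison of 4 with 10 libraries needed 186 separated regions for a call. With lists of equal length 18 regions were found in and 2 were missing from the central libraries alone, with the strongest 50% of each list 10 and 5, and with equal lengths by width 16 and 5. The separated regions numbered 59, 64, 66, 56 and 64 without D4 replicate 1, D4 replicate 2, D5 replicate 1, D5 replicate 2 and D6 replicate 2. Within 1 naming style, 359 regions separated the central domains, the most of 21 divisions.

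Tagged nuclei were compared with whole embryos of the same strains to ask what the pull-down of a subset of nuclei changed in common. The region 2L 19178301–19178520 was missing from all 8 tagged libraries and found in all 8 whole-embryo libraries (Fisher's exact p = 0.000155, adjusted p = 1), and it was named after its values were seen. Tagged nuclei and whole embryos of the same strain overlapped by 80.9% ± 1.60 (SD, n = 8 pairs) and shared a naming style. Whole embryos overlapped with each other by 82.3% ± 1.07 within a style (SD, n = 12 pairs) and by 81.2% ± 1.98 in all (SD, n = 28 pairs), and tagged nuclei with whole embryos of other strains by 78.3% ± 2.23 within a style (SD, n = 36 pairs) and 76.5% ± 3.09 in all (SD, n = 104 pairs). Fisher's exact test on 9055 regions gave 0 calls, with 273 regions at an unadjusted p under 0.05, of which 75 were found more and 198 less often in tagged nuclei. The separated region was not kept with all 14 tagged libraries, where the count was 0, and the count was 2, 4 and 2 without the whole-embryo libraries D4 replicate 1, D4 replicate 2 and D7 replicate 2.

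Each domain was then compared with the 8 whole-embryo libraries to ask which regions are open in a band of the embryo but not detected in the whole, or the reverse. Regions missing from both libraries of a domain and found in all 8 whole-embryo libraries were most numerous in D6 (612), D3 (459) and D7 (320), followed by D2 (205), D4 (125), D5 (120) and D1 (85). The count was above that of most or all other choices of 2 of the 10 libraries in every domain, with exact one-sided p = 0.0222, the smallest that 45 choices can give, in D2 to D7 (adjusted p = 0.0259) and p = 0.0444 in D1 (adjusted p = 0.0444). Among whole-embryo libraries alone, at most 85 regions were missing from both libraries of any of the 28 pairs and found in the other 6. Of the 1183 regions lost in any domain, 59.8% were lost in 1 domain and 24.3% in 2. With lists of equal length D6 lost 307, D3 276 and D7 186 regions, and with equal lengths by width D3 lost the most (205), followed by D6 (156), D2 (143) and D7 (133). D2, D3 and D6 had no whole-embryo lists of their own strains. Each had 1 list of a naming style that no whole-embryo list had, and these lacked 1110, 1497 and 1179 of the 13926 regions found in all 8 whole-embryo lists. Domain, strain and this possible batch could not be told apart there.

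The 4 domains with the most lost regions had the 4 lowest values of the authors' -log10 q, a relation computed after the counts were seen. It did not hold for the authors' fold. The mean of the median fold of both lists was 2.87 in D7, 2.84 in D2 and 2.80 in D3, against 2.71 in D4, 2.66 in D6, 2.64 in D5 and 2.63 in D1. The mean of the median -log10 q of both lists was 21.6 in D6, 22.5 in D3, 25.1 in D2 and 31.9 in D7, against 35.7 in D1, 42.2 in D5 and 42.5 in D4. Over the 7 domains, Spearman's rho between this value and the number of lost regions was -0.821 (exact permutation, two-sided, p = 0.0341, adjusted p = 0.0341) and Pearson's r was -0.815 (exact p = 0.0292, adjusted p = 0.0587), and without D4 and D5 r was -0.795 (exact p = 0.133). D2, D3 and D6 had no list of the first naming style, whose lists had the highest medians, so this relation was not free of style. Within 1 naming style, with 1 tagged library per domain, libraries with a lower median -log10 q lacked more of the 13926 regions found in all 8 whole-embryo libraries, from 1376 in D6 replicate 1 to 261 in D2 replicate 1 and in D5 replicate 2. Spearman's rho was -0.937 (exact permutation, two-sided, n = 7, p = 0.00476, adjusted p = 0.0238), Pearson's r was -0.825 (exact p = 0.0194, adjusted p = 0.0587), and without D5 replicate 2 and D6 replicate 1 r was -0.819 (exact p = 0.0417). In all, 5 such relations were computed, 3 of them for the lost counts under other settings.

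Regions found in both libraries of a domain and in no whole-embryo library numbered 207 in D4, 116 in D1, 97 in D3, 83 in D5, 39 in D7, 24 in D2 and 7 in D6. None of these 7 counts passed (exact one-sided permutation, adjusted p from 0.156 to 0.867), and a pair of whole-embryo libraries held up to 234 regions that the other 6 lacked. With lists of equal length the gained counts passed in D1 (93), D3 (187), D4 (174), D5 (77) and D7 (112), each with an exact adjusted p of 0.0311, but 0 of the 7 passed with equal lengths by width or with the strongest 50% of each list (smallest exact adjusted p = 0.0519). The lost count of D1 did not pass with the strongest 50% of each list (47) or with equal lengths by width (69). Leaving out a library of the domain raised the counts, since fewer lists then had to hold or lack a region, to as many as 839 gained in D1 without replicate 2 and 1497 lost in D3 without replicate 1.

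**Figure D5:**
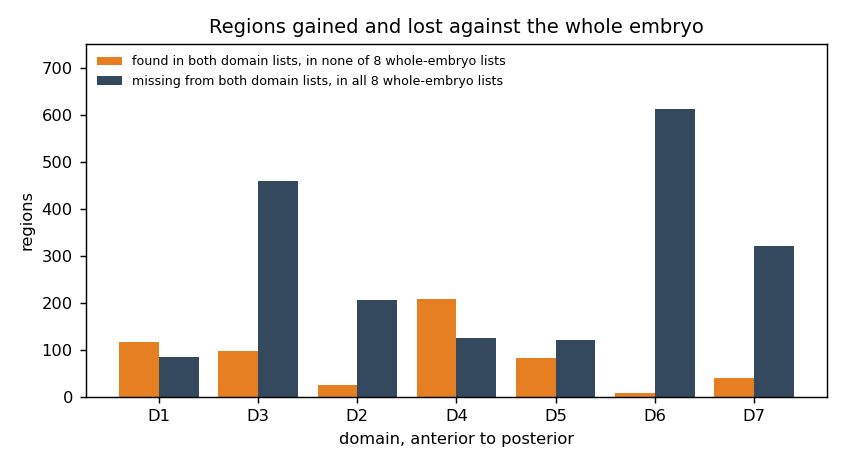
Number of regions (vertical axis) found in both libraries of a domain and in none of 8 whole-embryo libraries (orange), or missing from both and found in all 8 (dark), by domain from anterior to posterior (horizontal axis). Lost regions were most numerous in D6 (612) and gained ones in D4 (207), while D3 came first for lost regions with equal lengths by width (205) and for gained regions with equal lengths (187).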

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

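Some tests were chosen only after those results had been seen, unlike the naming-style test and the other tests on lost regions. They were the splits of the libraries and domains and the comparison by strain of peaks outside the main chromosome arms. The equal-length count for the anterior separation and the relation of lost regions to detection and to random draws were also chosen then. In 36 combinations of a group of 4 to 8 libraries and a measure, 0 libraries stood apart from their group, a weak check in groups of this size. Tagged lists held 133 to 295 peaks outside the main chromosome arms and whole-embryo lists 235 to 372, so no tagged list exceeded the highest control. By strain, tagged nuclei had fewer of these peaks in 8 of 8 strains, by a mean of -65.5 ± 22.9 (SD, n = 8; exact sign-flip test, two-sided, p = 0.00781, adjusted p = 0.0156), and as a share of the list they were lower in 7 of 8, by a mean of -0.283 ± 0.155 percentage points (SD, n = 8; exact p = 0.0156, adjusted p = 0.0156).

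The splits say nothing about the numbers of called regions, since any split gives at least the real 0 (100 of 100 in each of the 4 comparisons, highest other 0). For fully separated regions, 1 of 100 splits reached the anterior 53 (highest other 7), 1 of 100 the posterior 17 (highest other 8) and 2 of 100 the central 36 (highest other 60), but most of these splits part the libraries of a domain, which resemble each other. The split with 60 put the 4 longest tagged lists (replicate 1 of D1, D2, D4 and D5) against the other 10. With lists of equal length this split gave 5, so differences that go with list length can separate regions. The lists of D1, D4 and D5 were also of the first naming style, with median -log10 q of 44.8, 55.0 and 50.1. Length was therefore not told apart from style and detection. With the libraries of a domain kept together, the anterior grouping gave the most regions (53, 1 of 35 divisions, highest other 10). The central grouping also gave the most (36, 1 of 21, highest other 23). These are the smallest shares that 35 and 21 divisions allow, and they were not adjusted for 3 groupings. Chance was therefore argued against, but not excluded, for the anterior grouping. For the central grouping the evidence was weaker, since with lists of equal length the count was 20 against 16 for D1 and D3. Chance could not be excluded for the posterior grouping, as 3 of 21 reached 17, with 36 for D4 and D5 and 23 for D1 and D3. Nor could it be excluded for the 1 region separating tagged nuclei from whole embryos, which 7 of 100 splits matched, the highest other being 1. The 50 anterior calls with the strongest 50% of each list were reached by 1 of 100 splits and 1 of 35 divisions, the real ones, and the highest other was 0.

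The separation of D1, D2 and D3 from the other domains was weighed against 3 technical explanations. Grouping of the domains by chance was argued against, but not excluded, by 1 of 35 divisions, the smallest share possible, reaching 53 regions. The next was 10 for D4, D5 and D7, and the 3 domains with even-skipped enhancers gave 6. Unequal list lengths were argued against by the 49 separated regions with lists of equal length, where no other division passed 8. Naming style of the libraries was argued against by the 7 libraries of 1 style, where 1 of 35 divisions, the real one, reached 236 regions, although the highest other, D2, D4 and D5, gave 188. A difference in accessibility between anterior and more posterior nuclei may underlie the pattern, as a hypothesis. Differences in the transgenic strains were checked against whole-embryo lists for D1 only, where 14 of 24 anterior-missing regions were found in every whole-embryo list. D2, D3 and D6 had no whole-embryo lists.

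The regions lost in single domains against the whole embryo were weighed against 3 technical explanations. Unequal list lengths as the whole cause were argued against by 6 of 7 domains losing more at equal lengths than the highest pair of whole-embryo libraries (109). However, D5 (113) and D4 (122) were only a little above that pair, D1 lost 80 and the count of D6 dropped from 612 to 307. A pull-down step acting alike in every domain as the whole cause was argued against by 5.24% of 1183 lost regions being lost in at least 4 of 7 domains, but random draws of regions of like strength gave at most 0.491% and 19 of 21 pairs of domains shared more lost regions than such draws at an adjusted permutation p under 0.05 (over all 21, from 1.23 times the mean draw for D3 and D5 to 15.3 times for D4 and D5), so as part of the cause it stays open. Weaker detection in some libraries goes with the losses, as libraries of 1 naming style with a lower median -log10 q lacked more regions (Spearman's rho -0.937, exact permutation, n = 7, p = 0.00476, adjusted p = 0.0238). It is a candidate explanation for much of the pattern, and closing of regions in the nuclei of a band remains an untested alternative. For D2, D3 and D6, differences of strain and naming style could not be told apart from those of domain.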

How the results depend on the processing

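Ranking by width, the 100 kb windows, the fully separated regions, the results on the strongest 50% of lists beyond the first, naming style as strata and left-out libraries for domain-variable, gained and lost regions were chosen after seeing the data. Of 541 alternative values, 419 kept their direction and side of the threshold, or stayed within their spread or 1.5 times the count, and 0 reversed. This total is not a measure of stability, since part of the values could not have changed. Leaving out a library, or using strata, left too few separated regions for a call in any comparison. Counts also cannot fall below 0, which limits what could reverse. The overlap of 50% moved nothing, since merged regions contain whole peaks. Unknown read depth limits all counts, because a missing peak may be an undetected one; with lists of equal length the posterior separated regions were 7 in place of 17.

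In the main setting the posterior, central and tagged comparisons needed 186, 186 and 29 separated regions for a call and had 17, 36 and 1. They gave 0 calls under all alternatives run. With the replicate block or naming style as strata this says nothing about stability, since a call then needed 74 to 1474 regions at the smallest possible p and 1 to 70 were there, and in the anterior comparison 152 and 443 against 53. Anterior calls were 0 with equal lengths, bins, no filter, all sequences, central domains left out, replicate block and naming style as strata. They were 50 with the strongest 50%, 47 with the widest 50% and 54 with equal lengths by width. Without the filter 24204 regions were tested and with bins 20742, against 9284 in the main setting, which raises the number of separated regions needed. Leaving out the central domains raises the smallest possible p. The number needed was not computed for these settings, so their 0 calls cannot be read as stability. The 50 calls were 38 with the strongest 40%, and ended at 0 with 60%, 70% and 80%, with equal lengths of 50% of the shortest list, with the replicate block, with naming style as strata and without any 1 library. The replicate block, the strata and a left-out library raise the smallest possible p, so that 102, 296 and 70 to 95 separated regions were needed against 50, 50 and 50 to 66; the cause was not tested for the others.

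Fully separated regions were 128 (anterior), 38 (posterior) and 59 (central) with bins of 500 bp and 119 in the anterior comparison without the central domains. The posterior count was 7 with equal lengths, 10 with the strongest 50%, 11 with equal lengths by width and 6 with the widest 50%, and the central count 20, 15, 21 and 12. Tagged nuclei against whole embryos gave 2 with equal lengths and 0 with the strongest 50%, equal lengths by width, the widest 50% and all 14 tagged libraries. Domain-variable regions were 3280 with the strongest 50% and 11817 with bins. Windows called in the anterior comparison were 8 with equal lengths, 15 with equal lengths by width and 6 with 200 kb windows. Without the central domains fewer lists had to agree, and bins can count a region more than once. How much of those shifts this explains, and the cause of the others, was not tested.

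With equal lengths, gained regions were 93 (D1), 75 (D2), 187 (D3), 174 (D4), 77 (D5), 64 (D6) and 112 (D7), and lost regions 276 (D3), 307 (D6) and 186 (D7). With the strongest 50%, gained regions were 92 (D4), 26 (D5) and 19 (D7), and lost regions 47 (D1), 97 (D2), 211 (D3), 72 (D5), 235 (D6) and 159 (D7). With equal lengths by width, gained regions were 47 (D2), 174 (D3), 66 (D6) and 127 (D7), and lost regions 69 (D1), 205 (D3), 156 (D6) and 133 (D7). With whole embryos of the same strains only, which makes fewer lists decide, D1, D4, D5 and D7 gained 433, 415, 306 and 148 and lost 365, 435, 411 and 813 regions. The cause of the other shifts was not tested.

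Leaving out 1 library or domain gave 53 to 84 separated regions (anterior), 17 to 44 (posterior), 36 to 66 (central) and 1 to 4 (tagged), 0 to 0 calls in each comparison (0 left-out libraries left enough separated regions for a call), 5885 to 7441 domain-variable regions, 2.74 to 3.65 points of replicate similarity, -926 to -327 peaks between tagged nuclei and whole embryos, and 0 to 14 windows (14 in the anterior comparison without D6 replicate 1). Gained regions ran from 123 to 839 (D1), 25 to 260 (D2), 99 to 306 (D3), 213 to 806 (D4), 85 to 625 (D5), 7 to 236 (D6) and 40 to 281 (D7). Lost regions ran from 90 to 496, 218 to 1110, 492 to 1497, 129 to 447, 125 to 282, 647 to 1376 and 330 to 867 in the same order. The alternatives for gene lists and motif content were not run, as neither was tested.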

Other observations

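All tests in this part were chosen after the results had been seen. A stretch of 2R from 20710053 to 20724339 held 4 regions found in all anterior libraries and no other tagged library. Of its 15 regions, anterior libraries held 8 ± 3.22 (SD, n = 6, range 5 to 14), the other tagged libraries 0.125 ± 0.354 (SD, n = 8, range 0 to 1) and whole embryos 1 ± 0.926 (SD, n = 8, range 0 to 3). D3 replicate 2 held the most, 14, and all 4 separated regions were found in at most 2 of 8 whole-embryo libraries. By general knowledge of the dm3 map, and not by an annotation used here, the 3R stretch with 9 anterior-missing regions lies in the bithorax complex of Hox genes, which pattern the trunk and abdomen, and the one with 11 central-found regions at Antennapedia, a Hox gene of the thorax.

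The gathering of separated regions on 3R was weighed against chance position and strain differences. Of 10000 random sets of as many tested regions, 0 held a group of regions at most 100 kb apart as large as the 9 anterior-missing ones (largest 4) or the 11 central-found ones (largest 5), each a permutation p of 0.0001, the smallest possible, and an adjusted p of 0.0002. A deletion in the transgenic strains of D1 was argued against by 7 of the 9 regions being found in both whole-embryo lists of those strains, while D2 and D3 had no such lists. For D2 and D3, a deletion of the whole stretch was argued against by the 26 of its 107 regions found in all 22 libraries. Smaller deletions at the 9 regions were not tested there. A sequence variant of the transgenic strains of D4 and D5 was argued against by 100% of the 11 regions being missing from at least 1 whole-embryo list of those strains. Long stretches that are more open in some bands of the embryo than in others may therefore explain the gathering, as a hypothesis found and tested in the same data.

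The 4 anterior-found regions on 2R formed a group as large as 12 of 10000 random sets held (permutation p = 0.0013, adjusted p = 0.00173), while the number of anterior-found regions in any group, 6 against a random median of 2, did not pass (permutation p = 0.0420, adjusted p = 0.0560). The largest group of the 17 posterior-missing regions had 2 members (permutation p = 0.252).

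Counts of regions per 100 kb window, scaled to list length, were compared over 1062 windows in the anterior, posterior and central comparisons and over 1069 in that of tagged nuclei. At 3R 12500001–12600000 anterior libraries held 26.5 ± 5.43 regions (SD, n = 6) and the other tagged libraries 53.9 ± 7.53 (SD, n = 8), and at 3R 5700001–5800000 they held 10.7 ± 1.63 and 26.8 ± 5.28. At 2R 20700001–20800000 the anterior libraries held more, 26.3 ± 5.47 against 15.1 ± 1.13. These windows had an exact permutation p of 0.000333, the smallest possible, and an adjusted p of 0.0589, and whole embryos held means of 40.4, 17.9 and 16.6 regions there. The test treated libraries of a domain as independent, so these p-values are lower than they should be. The exact permutation test called 0 windows in each of the 4 comparisons, with 160, 133, 135 and 99 windows at an unadjusted p under 0.05 for anterior, posterior, central and tagged. The splits of the libraries say nothing about these counts, since any split gives at least 0 (100 of 100 in each comparison, highest other 0). Calls were made in the anterior comparison with equal lengths (8), with equal lengths by width (15), with 200 kb windows (6) and without D6 replicate 1 (14).

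Regions found in both libraries of 1 domain and in none of the other 12 tagged libraries numbered 125 in D1, 66 in D4, 59 in D5, 24 in D7, 23 in D3, 8 in D2 and 0 in D6. Regions missing from both libraries of 1 domain alone numbered 58 in D6, 41 in D7, 30 in D3, 17 in D2, 8 in D5, 2 in D4 and 1 in D1. None of these counts passed (exact one-sided permutation over 91 pairs of libraries, smallest adjusted p = 0.154 for found and 0.192 for missing regions), and pairs from different domains reached 198 and 95.

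Domain-variable regions were spread over all arms, with 2.43% on chromosome 4 against 1.63% of the regions found in all 14 tagged libraries (odds ratio 1.51, Fisher's exact test, adjusted p = 0.00347), and 26.3% against 24.0% on 3R (odds ratio 1.13, adjusted p = 0.00672). Regions are not independent of their neighbours, so these p-values are lower than they should be.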
